A study of Oryza sativa Indica Group with 18 samples.

How the data were processed

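RNA from whole seedlings, 7 days old, of 2 indica rice cultivars was measured on Affymetrix rice arrays, 18 in all, with 3 arrays labelled as biological replicates in each of 6 groups. Per the labels' protocols, seedlings were grown hydroponically, heat was given in light at about 40% relative humidity, controls stood at 28 ± 1 °C for 3 h, and 500 ng of total RNA per array was labelled with biotin by in vitro transcription from the 3' end. The deposited values are linear intensities per probe set, 1 column per array; the labels name GCOS as the only tool, and the method by which the authors summarized and scaled the intensity values is not given in the sources used here. The 37 °C groups are labelled as 37 °C for 1 h, and the 42 °C groups as 37 °C for 1 h followed by 42 °C for 2 h.

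Of 57381 probe sets, 123 Affymetrix control probe sets were left out and 57258 tested. Array medians lay within 0.037 log2 of each other, under the 0.1 allowed, so no further normalization was applied. Values were taken as log2 of intensity plus 16. A model with 6 group means was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3 (12 residual degrees of freedom, empirical Bayes with a variance trend), and 12 contrasts were taken: each heat step against control and the heat steps against each other within a cultivar, Annapurna minus IR64 at each step, and the Annapurna response minus the IR64 response. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 within the contrast and a difference of at least 2-fold (1 log2). Tests were two-sided. With 3 arrays against 3, an exact permutation test of a single gene cannot give a p below 0.1, so only limma p values are given. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for annotation and figures.

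Probe sets were named from the annotation of the array: 22436 matched exactly 1 gene, 95 several and 34727 none. The 17905 genes with a probe set of their own were all found in the reference gene table, 2455 carried a name other than a locus or clone number, and 3444 had over 1 probe set. A gene's representative was its probe set with the highest mean over the 18 arrays, and map positions were not used here. Named genes followed a rule: for each heat step against control, the 8 largest rises and 6 largest falls among named genes called and without overlap of the 3 arrays against 3, which chance gives to 10% of genes; for each cultivar difference and each difference of responses, the 6 largest each way, without the overlap condition for the latter; and in each list the 3 largest called members and the uncalled member with the highest mean level. Planned whatever their result were CLPB1 (HSP101), the 5 HSFA2 factors, DREB2A, DREB2B, CCA1 (also named LHY), OsPRR1, OsPRR37, OsPRR73, OsPRR95 and GI for each heat step against control; the annotation names no OsPRR59. AMY1.1 and EP3A on single arrays, and other examples outside these, were taken up after their values were seen. Where 2 genes carry the same symbol, as with AOS, the other name is given.

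The comparisons, thresholds, named gene rule and first set of alternatives were fixed before the data were examined. The gene lists had been planned as searches of gene descriptions, which the annotation does not carry, so they were rebuilt as patterns on gene symbols and synonyms after the annotation was seen and before any test. Some planned lists, such as HSP70 chaperones, found too few named genes, and thioredoxins, CCCH, A20/AN1, calcium kinase, chitinase and cytokinin lists were added. The 38 lists were: small heat shock proteins, HSP90 chaperones, HSP100 and Clp, DnaJ proteins, heat stress transcription factors, ER protein folding, ubiquitin and proteasome, ascorbate and glutathione defence, glutathione S-transferases, thioredoxins and glutaredoxins, raffinose and trehalose synthesis, LEA and dehydrin, PP2C and ABA receptors, jasmonate, auxin response, ethylene response and DREB factors, WRKY factors, NAC factors, CCCH zinc finger proteins, stress associated A20/AN1 proteins, circadian clock, calmodulin and CML, CBL-interacting and calcium-dependent kinases, photosynthetic light reactions, Calvin cycle, chlorophyll synthesis, root markers, seed and endosperm markers, class III peroxidases, expansins and XTH, cellulose and lignin synthesis, aquaporins, cytosolic ribosomal proteins, histones, cell division, chitinases, cytokinin signalling, and actin and tubulin reference genes; 3 measured genes were the smallest list tested. Lists hold named genes only, and a gene may stand in several. HSFA2C and HSFA2D share their loci with other gene symbols in the annotation. Each list was tested by limma camera with a preset correlation of 0.01 on representative probe sets, Benjamini-Hochberg adjusted over the 38 lists within a comparison; camera with an estimated correlation, and fry, which tests whether a list's genes move on balance 1 way, were alternatives. Counts adjusted over the list alone carry no fold threshold.

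Alternatives tried were quantile normalization, median centring, pseudocounts of 1 and 64, only the 28629 probe sets at or above the median level, no variance trend, array weights, the replicate number as a block, only the compared groups in the fit, no fold threshold, 1 probe set per gene and leaving out each array. Chosen after the data were seen were leaving out control replicate 3 of both cultivars, and only the 20348 probe sets with a group mean above 50 in both cultivars. The procedure was tested on simulated data with the arrays' own spread for Annapurna 37 °C against control: 50 of 50 probe sets were called at each simulated log2 of 1.2, 1.5, 2 and 3, and 0 of 57058 unchanged probe sets. In the same simulation the 1 shifted list was called and 0 of 37 others. Its noise was drawn independently for each probe set and its lists at random. It therefore says nothing on list calls where the genes of a list are correlated.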

Results

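Transcript levels in whole seedlings of the rice cultivars Annapurna and IR64 were measured on 18 arrays. Each cultivar gave 3 groups of 3 arrays labelled as biological replicates. The control stood at 28 °C for 3 h, 1 group was held at 37 °C for 1 h, and 1 group at 37 °C for 1 h and then at 42 °C for 2 h; the last is called 42 °C here. The series title sets a heat tolerant against a heat susceptible cultivar, and the sources used here do not say which is which, so the cultivars are compared by name. The 37 °C groups were taken after 1 h and the controls after 3 h, so temperature and elapsed time could not be separated at 37 °C. The 42 °C groups were taken after 3 h, so the same limit holds for every comparison of 42 °C with 37 °C. Log2 differences are given ± SE from a fit over all 18 arrays, intensities as mean ± SD, and n = 3 arrays in every group. "Rose", "fell", "higher" and "lower" are used of genes with a limma adjusted p under 0.05 and at least 2-fold difference. A list is said to shift up or down where the test of the whole list was called in that direction, and the count of its called members stands beside it. Over all 17905 genes the share called was 10.3, 8.9 and 9.1% in Annapurna (37 °C, 42 °C and 42 °C against 37 °C) and 9.2, 11.5 and 6.4% in IR64. It was 6.1, 5.4 and 5.6% between cultivars (control, 37 °C and 42 °C). For the differences of responses it was 2.8, 5.5 and 5.1% (37 °C, 42 °C and 42 °C against 37 °C). An intensity of 16 was added before the log, so the size of a difference from a group near background depends on that amount: HSP26.7 in Annapurna at 37 °C stood at log2 10.02 with 1 added and 6.81 with 64, and OsTPP7 between the controls of the cultivars at 8.56 and 5.07, against 8.45 and 6.76 with 16.

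Between 34.2 and 35.3% of the probe sets on an array exceeded an intensity of 50, and the number of arrays limits the precision of each value. Correlations across probe sets, which are not independent replicates, ran from 0.997 to 0.999 between arrays of 1 group and from 0.961 to 0.987 between arrays of different groups. The first principal component, with 38.2% of the variance, parted the cultivars, and the second, with 30.5%, parted controls from heated arrays. AMY1.1, an alpha-amylase gene known from germinating grain, stood out on single arrays: it read 3532 on IR64 control replicate 3 against 37.9 and 41.6 on the other IR64 controls, and 124 on Annapurna control replicate 3 against 5.49 and 5.48. On the IR64 42 °C arrays AMY1.1 read 8767 to 10078, and on all 37 °C arrays and the Annapurna 42 °C arrays it read 5.41 to 5.65. The cysteine proteinase gene EP3A, also of germinating grain, read 102 on IR64 control replicate 3 and 41.5 to 52.3 on the IR64 42 °C arrays. RNA from grain tissue may thus enter every comparison with the IR64 42 °C group. There it cannot be told apart from an effect of heat or cultivar. Of 18 seed and endosperm markers, 4 rose in that group against control and 0 fell. Their list was not called (median log2 -0.010, adjusted p = 0.84). The mean signal of the added hybridization control creX was 33794 in Annapurna controls and 32138 in IR64 controls, 30192 and 26520 at 37 °C, and 23496 and 23868 at 42 °C. Of the signs of RNA quality, the log2 ratio of 3' to 5' actin signal was 5.54 ± 0.67 in Annapurna controls, 5.32 ± 0.12 at 37 °C and 5.24 ± 0.14 at 42 °C, and 4.77 ± 0.23, 4.99 ± 0.19 and 5.14 ± 0.095 in IR64, with 6.31 on Annapurna control replicate 1. The 18S ribosomal RNA signal was 135 ± 107, 407 ± 234 and 220.1 ± 96.9 in Annapurna and 205 ± 111, 389 ± 143 and 143 ± 95.9 in IR64, so it was highest on average at 37 °C in both cultivars, with 14.5 on Annapurna control replicate 1.

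**Figure D1:**
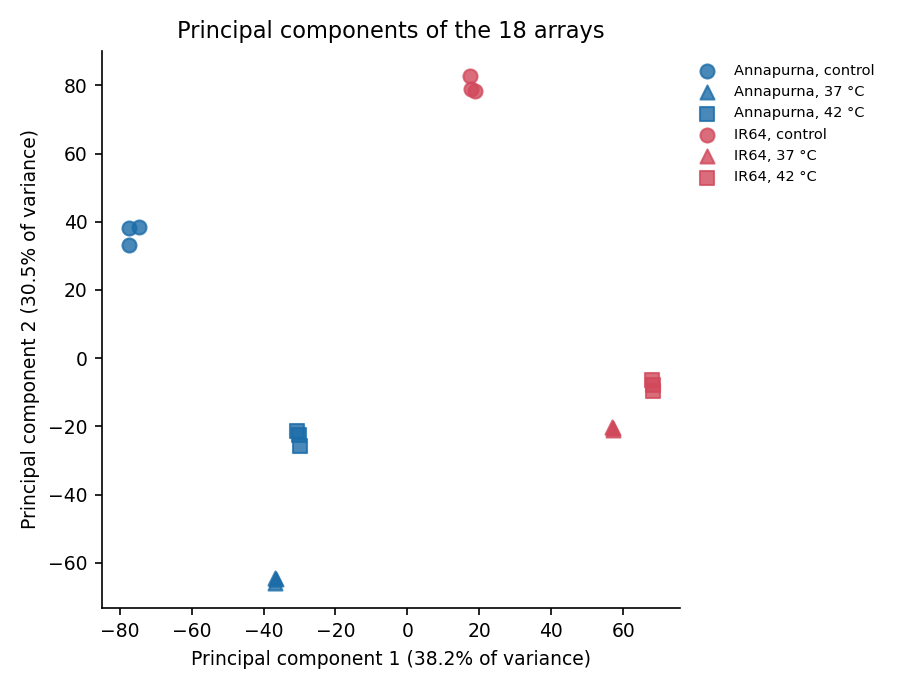
Principal components of the 18 arrays, each point 1 array, with colour for the cultivar and shape for the step, and the axes unitless scores. Component 1 holds 38.2% of the variance and parts Annapurna from IR64, and component 2 holds 30.5% and parts the controls from the heated arrays.

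The first question was which transcripts changed in Annapurna within 1 h at 37 °C. Small heat shock proteins, which bind unfolding proteins, made the largest rise: 17 of 19 rose and 0 fell, or 19 and 0 adjusted over the list alone. With median log2 4.80 the list had adjusted p = 1.2e-19, and adjusted p = 1.0e-05 with an estimated correlation. HSP26.7 rose from an intensity of 6.56 ± 0.350 to 7869 ± 92.5 (log2 8.45 ± 0.049, adjusted p = 2.0e-19), HSP18.0 by log2 8.69 ± 0.084, HSP16.9B by 7.46 ± 0.076, HSP23.2 by 7.00 ± 0.073, HSP18.6 by 6.05 ± 0.13 and HSP16.9A by 6.03 ± 0.092; HSP18.8 was at 0.94 ± 0.042 and was not called, and 2 further probe sets of HSP18.0 were not called either. HSFA2A, a heat stress transcription factor, rose from 37.99 ± 3.93 to 7124 ± 267 (log2 7.05 ± 0.086), with HSFA2C at 4.42 ± 0.16 and HSFB2B at 3.27 ± 0.11. Of the heat stress transcription factors, 6 of 20 rose and 1 fell, or 15 and 3 adjusted over the list alone. With median log2 0.68 the list had adjusted p = 6.2e-04, and adjusted p = 0.17 with an estimated correlation. HSFA2B, HSFA2D and HSFA2E, of the same subfamily, stood at 0.75 ± 0.091, 0.38 ± 0.11 and 0.74 ± 0.067, not called. DREB2A rose by 1.27 ± 0.12, and DREB2B was at 0.47 ± 0.10, not called. CLPB1, the cytosolic HSP101 that resolves protein aggregates, rose from 209.5 ± 35.9 to 8580 ± 393 (log2 5.26 ± 0.083), and CLPB-M by 3.73 ± 0.099. In the HSP100 and Clp list 4 of 8 rose and 0 fell, or 5 and 1 adjusted over the list alone. With median log2 1.19 the list had adjusted p = 0.022, and adjusted p = 0.091 with an estimated correlation. Among the HSP90 chaperones 1 of 3 rose and 0 fell, or 3 and 0 adjusted over the list alone, the riser being HSP81-1 at log2 1.06 ± 0.049. With median log2 0.43 the list had adjusted p = 0.031, and adjusted p = 0.13 with an estimated correlation. After quantile normalization HSP81-1 was at 0.98 and the list at adjusted p = 0.057, neither called. In the ER protein folding list 9 of 24 rose and 0 fell, or 17 and 4 adjusted over the list alone. With median log2 0.60 the list had adjusted p = 9.7e-06, and adjusted p = 0.062 with an estimated correlation. The protein disulfide isomerase gene OsPDIL2-3 rose by 3.36 ± 0.058 and DER1 by 2.71 ± 0.089. Of the DnaJ proteins, 2 of 5 rose and 0 fell, or 4 and 1 adjusted over the list alone. With median log2 0.57 the list had adjusted p = 0.031, and adjusted p = 0.13 with an estimated correlation. DJC27, which stands in both lists, rose by 3.56 ± 0.058.

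LEA and dehydrin genes, whose products protect drying cells, also rose in Annapurna at 37 °C: 9 of 9 rose and 0 fell, or 9 and 0 adjusted over the list alone. With median log2 2.32 the list had adjusted p = 4.6e-07, and adjusted p = 0.083 with an estimated correlation. RAB16B rose from 891 ± 80.5 to 11990 ± 335 (log2 3.73 ± 0.082), RAB16D by 3.22 ± 0.17 and OsPM19L1 by 3.04 ± 0.13. The homeobox gene HOX24 rose by log2 6.30 ± 0.066. The largest falls were in PDX12 (-4.61 ± 0.072), DREB1B (-3.63 ± 0.13), NIA1, a nitrate reductase gene (-3.42 ± 0.039, its other probe set not called), the beta-glucosidase gene BGLU19 (-2.98 ± 0.15), the sugar transporter gene MtN3-like (-2.95 ± 0.14) and 4CL2 of phenylpropanoid synthesis (-2.91 ± 0.073). Cell division genes shifted down as a list: 1 of 65 rose and 8 fell, or 11 and 36 adjusted over the list alone. With median log2 -0.22 the list had adjusted p = 0.031, and adjusted p = 0.48 with an estimated correlation, and adjusted p = 0.056 after quantile normalization. MCM5, of the replicative helicase, fell (log2 -1.66 ± 0.066), as did ORC5 (-1.54 ± 0.18), while the kinesin gene KIN14A rose by 1.49 ± 0.078. Over all probe sets 1650 probe sets were higher and 1285 lower in Annapurna at 37 °C. Of the 8 lists called in this comparison, small heat shock proteins alone kept their call with an estimated correlation, and over the 12 comparisons the 8 of 89 list calls that held were all of that list.

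The same step in IR64 moved many of the same probe sets. Of 1650 higher in Annapurna and 1551 higher in IR64, 1091 were shared, where 44.7 would be shared by chance, and of 1285 and 1158 lower, 663 were shared against 25.99; the 12 arrays of the 2 comparisons do not overlap. Small heat shock proteins rose again, 16 of 19 rose and 0 fell, or 19 and 0 adjusted over the list alone. With median log2 5.30 the list had adjusted p = 7.8e-19, and adjusted p = 1.3e-05 with an estimated correlation. HSP18.0 rose from 32.2 ± 3.99 to 26870 ± 570.5 (log2 9.13 ± 0.084), HSP26.7 by 8.56 ± 0.049, HSP23.2 by 7.99 ± 0.073, HSP18.6 by 7.01 ± 0.13, HSP16.9B by 6.80 ± 0.076 and HSP16.0 by 6.23 ± 0.051. HSP18.1 rose from 121 ± 16.3 to 33560 ± 1640 (log2 7.95 ± 0.13), and HSFA2A from 21.8 ± 3.62 to 5953 ± 394 (7.30 ± 0.086). Heat stress transcription factors shifted up as a list (7 of 20 rose and 1 fell, or 14 and 4 adjusted over the list alone). With median log2 0.49 the list had adjusted p = 0.008, and adjusted p = 0.2 with an estimated correlation. HSFA2C rose by 4.49 ± 0.16 and HSFA2E by 1.06 ± 0.067, while HSFA2B (0.62 ± 0.091), HSFA2D (0.31 ± 0.11), DREB2A (0.49 ± 0.12) and DREB2B (0.51 ± 0.10) were not called. CLPB1 rose by log2 5.55 ± 0.083 within HSP100 and Clp (4 of 8 rose and 0 fell, or 5 and 2 adjusted over the list alone). With median log2 1.04 the list had adjusted p = 0.021, and adjusted p = 0.12 with an estimated correlation. BIP4, an ER chaperone gene, rose by 3.16 ± 0.14 and DJC27 by 4.16 ± 0.058; in ER protein folding 8 of 24 rose and 0 fell, or 16 and 3 adjusted over the list alone. With median log2 0.60 the list had adjusted p = 1.0e-04, and adjusted p = 0.12 with an estimated correlation. The HSP90 chaperones shifted up as a list (1 of 3 rose and 0 fell, or 3 and 0 adjusted over the list alone). With median log2 0.36 the list had adjusted p = 0.037, and adjusted p = 0.12 with an estimated correlation. HSP81-1 rose by 1.08 ± 0.049. Among probe sets at or above the median level the list was at adjusted p = 0.057. LEA and dehydrin genes rose, 8 of 9 rose and 0 fell, or 9 and 0 adjusted over the list alone. With median log2 1.63 the list had adjusted p = 5.2e-05, and adjusted p = 0.12 with an estimated correlation. OsPM19L1 rose by 2.57 ± 0.13, and EM stood at 0.65 ± 0.27, reaching 1.005 and a call without IR64 control replicate 3. Of the seed and endosperm markers AMY1.3 rose by 4.69 ± 0.071 (its other probe set not called) and GLB1 by 1.29 ± 0.078 on these arrays, as did the seed-type tonoplast aquaporin gene OsTIP3;1 (2.37 ± 0.074). Jasmonate genes shifted down in IR64: 1 of 38 rose and 9 fell, or 4 and 25 adjusted over the list alone. With median log2 -0.41 the list had adjusted p = 0.012, and adjusted p = 0.12 with an estimated correlation. JAZ9, a repressor of jasmonate signalling, fell (log2 -3.20 ± 0.13), as did the 12-oxophytodienoate reductase genes OPR10 (-2.83 ± 0.095) and OPR5 (-2.19 ± 0.11). Cell division genes shifted down (1 of 65 rose and 5 fell, or 9 and 38 adjusted over the list alone). With median log2 -0.26 the list had adjusted p = 0.031, and adjusted p = 0.37 with an estimated correlation. OsPCNA fell (log2 -1.42 ± 0.045). Over all genes 9.2% were called at this step, so the count of called cell division genes was near that share. Without a fold threshold 8207 probe sets were higher and 21427 lower, so the counts over the list alone lean the way of all probe sets. The cold-response factors DREB1G (-4.36 ± 0.21) and DREB1B (-4.28 ± 0.13), the aluminium transporter gene Nrat1 (-3.23 ± 0.089) and NIA1 (-3.08 ± 0.039) fell as well. AMY1.1 fell (log2 -3.36 ± 1.19, adjusted p = 0.03), a value that rested on IR64 control replicate 3, without which it was -1.36 (adjusted p = 0.0709). Leaving out control replicate 3 of both cultivars gave the same difference with a call (adjusted p = 9.7e-09). Its call was also lost without any 1 of the IR64 37 °C arrays (adjusted p = 0.0605 to 0.0721), and leaving out 1 of the other IR64 controls gave -4.34 and -4.39. Over all probe sets 1551 probe sets were higher and 1158 lower.

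**Figure D2:**
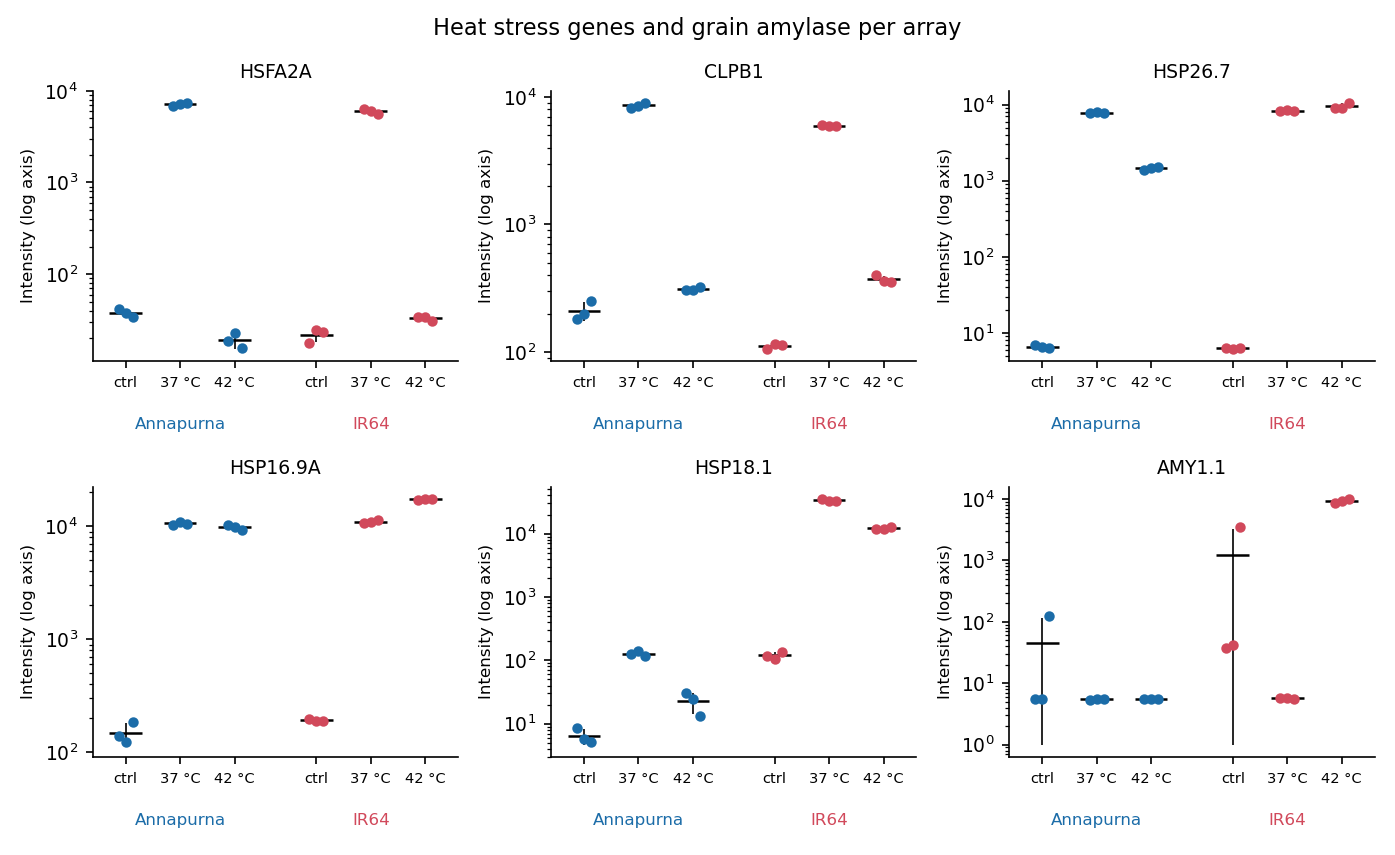
Intensity on a log axis of 5 heat stress genes and the grain amylase gene AMY1.1 in each group, with points for the 3 arrays, horizontal bars for means and vertical bars for ± 1 SD, whose lower ends stop at 1. HSFA2A averages 7124 in Annapurna and 5953 in IR64 at 37 °C and 19.1 and 33.1 at 42 °C, and HSP18.1 peaks at 128 in Annapurna and 33560 in IR64.

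At 42 °C, after 3 h as in the control, fewer heat genes of Annapurna stood above the control. Small heat shock proteins were still higher (13 of 19 rose and 0 fell, or 15 and 1 adjusted over the list alone). With median log2 1.08 the list had adjusted p = 4.0e-10, and adjusted p = 3.2e-04 with an estimated correlation. HSP26.7 read 1453 ± 74.3 (log2 6.02 ± 0.049), and HSP18.0, HSP16.9A, HSP23.2 and hsp17.9 rose by 5.97 ± 0.084, 5.92 ± 0.092, 4.75 ± 0.073 and 3.78 ± 0.11. HSFA2A was at 19.1 ± 3.71 (log2 -0.62 ± 0.086, not called), and of the heat stress transcription factors 0 of 20 rose and 4 fell, or 3 and 13 adjusted over the list alone, HSFB2A by -2.89 (median log2 -0.52, adjusted p = 0.067). CLPB1 (0.56 ± 0.083), HSFA2B (-0.28 ± 0.091), HSFA2C (0.11 ± 0.16), HSFA2D (0.90 ± 0.11), HSFA2E (0.031 ± 0.067), DREB2A (-0.32 ± 0.12) and DREB2B (0.74 ± 0.10) were not called. Of the LEA and dehydrin genes 2 of 9 rose and 2 fell, or 4 and 2 adjusted over the list alone: the list had median log2 0.39, adjusted p = 0.53. RAB16D rose by 3.16 ± 0.17, rab25 fell (log2 -1.17 ± 0.12), and RAB21 at 0.996 ± 0.15 was called only without Annapurna control replicate 3 (1.11) or Annapurna 42 °C replicate 3 (1.06). The lipid transfer gene LTP-2 rose by 3.08 ± 0.088 and osysl15, an iron uptake transporter gene, by 3.06 ± 0.089. The morning clock gene CCA1 fell from 12850 ± 1104 to 504 ± 27.9 (log2 -4.63 ± 0.059, its other probe set not called). DREB1B (-4.73 ± 0.13), DREB1G (-4.59 ± 0.21), PDX12 (-4.32 ± 0.072), BGLU19 (-4.17 ± 0.15) and JAZ13 (-4.04 ± 0.16) fell. The calmodulin list shifted down (1 of 26 rose and 6 fell, or 3 and 16 adjusted over the list alone). With median log2 -0.38 the list had adjusted p = 0.041, and adjusted p = 0.12 with an estimated correlation. CML31 fell (log2 -2.54 ± 0.13). Raffinose and trehalose synthesis genes shifted down (0 of 9 rose and 2 fell, or 0 and 7 adjusted over the list alone). With median log2 -0.45 the list had adjusted p = 0.041, and adjusted p = 0.19 with an estimated correlation. The list of catalase and other ascorbate and glutathione defence genes shifted up (2 of 21 rose and 1 fell, or 12 and 3 adjusted over the list alone). With median log2 0.16 the list had adjusted p = 0.041, and adjusted p = 0.38 with an estimated correlation. CAT-A rose by 1.39 ± 0.054. Class III peroxidases were higher too (2 of 3 rose and 0 fell, or 3 and 0 adjusted over the list alone). With median log2 1.31 the list had adjusted p = 0.041, and adjusted p = 0.28 with an estimated correlation. PRX112 rose by 1.84 ± 0.10. Histones shifted up as a list (0 of 6 rose and 0 fell, or 5 and 0 adjusted over the list alone). With median log2 0.43 the list had adjusted p = 0.041, and adjusted p = 0.4 with an estimated correlation. After quantile normalization the 5 lists besides the small heat shock proteins stood at adjusted p = 0.059 to 0.068 and were not called, and among probe sets at or above the median level all of them but the calmodulin list stood at 0.051. Over all probe sets 1137 probe sets were higher and 1503 lower in Annapurna.

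In IR64 at 42 °C small heat shock proteins were higher (15 of 19 rose and 0 fell, or 19 and 0 adjusted over the list alone). With median log2 2.73 the list had adjusted p = 2.6e-11, and adjusted p = 1.8e-04 with an estimated correlation. HSP26.7 read 9653 ± 823 (log2 8.76 ± 0.049), and HSP18.0, HSP23.2, HSP18.1, HSP16.9A and HSP16.9B rose by 6.83 ± 0.084, 6.72 ± 0.073, 6.47 ± 0.13, 6.38 ± 0.092 and 4.97 ± 0.076. CLPB1 rose by 1.60 ± 0.083 and HSFA2C by 1.86 ± 0.16, while HSFA2A (0.38 ± 0.086), HSFA2B (0.57 ± 0.091), HSFA2D (0.70 ± 0.11), HSFA2E (0.71 ± 0.067), DREB2A (-0.29 ± 0.12) and DREB2B (0.77 ± 0.10) were not called. LEA and dehydrin genes were higher (8 of 9 rose and 0 fell, or 8 and 1 adjusted over the list alone). With median log2 3.30 the list had adjusted p = 0.0022, and adjusted p = 0.23 with an estimated correlation. RAB16C rose by 4.43 ± 0.17, RAB16D by 4.08 ± 0.17 and RAB21 by 3.92 ± 0.15, while Dhn1 was at -0.64 ± 0.053. On these same arrays AMY1.1 rose by 5.39 ± 1.19, by 7.39 without IR64 control replicate 3, and by 4.37 and 4.42 without replicate 1 or 2. LTP-2 rose by 6.16 ± 0.088. Jasmonate genes shifted down (1 of 38 rose and 11 fell, or 6 and 24 adjusted over the list alone). With median log2 -0.32 the list had adjusted p = 0.0012, and adjusted p = 0.091 with an estimated correlation. JAZ9, JAZ10 and JAZ11 fell (log2 -4.45 ± 0.13, -4.14 ± 0.11 and -3.56 ± 0.088). Calvin cycle genes shifted down (0 of 7 rose and 2 fell, or 0 and 6 adjusted over the list alone). With median log2 -0.40 the list had adjusted p = 0.0066, and adjusted p = 0.23 with an estimated correlation. CFBP1 and FBPase, listed by symbol, fell (log2 -3.100 ± 0.072 and -2.28 ± 0.044), and their part in the Calvin cycle was not checked. NAC factors shifted down (0 of 8 rose and 2 fell, or 1 and 6 adjusted over the list alone). With median log2 -0.64 the list had adjusted p = 0.044, and adjusted p = 0.15 with an estimated correlation. Calmodulin genes shifted down as well (1 of 26 rose and 7 fell, or 5 and 15 adjusted over the list alone). With median log2 -0.26 the list had adjusted p = 0.035, and adjusted p = 0.1 with an estimated correlation. Neither list was called after quantile normalization (adjusted p = 0.082 and 0.069). DREB1G (-4.77 ± 0.21), DREB1B (-4.44 ± 0.13), PDX12 (-3.84 ± 0.072) and OsWRKY71 (-3.82 ± 0.097) fell, and CCA1 fell from 6393 ± 56.7 to 589.8 ± 33.3 (-3.41 ± 0.059). Over all probe sets 2088 probe sets were higher and 1473 lower, or 58.6% of calls higher; after quantile normalization 1624 were higher and 1786 lower, or 47.6%. Of the probe sets higher in Annapurna and in IR64, 680 were shared against 41.5 by chance, and of those lower, 764 against 38.7.

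**Figure D3:**
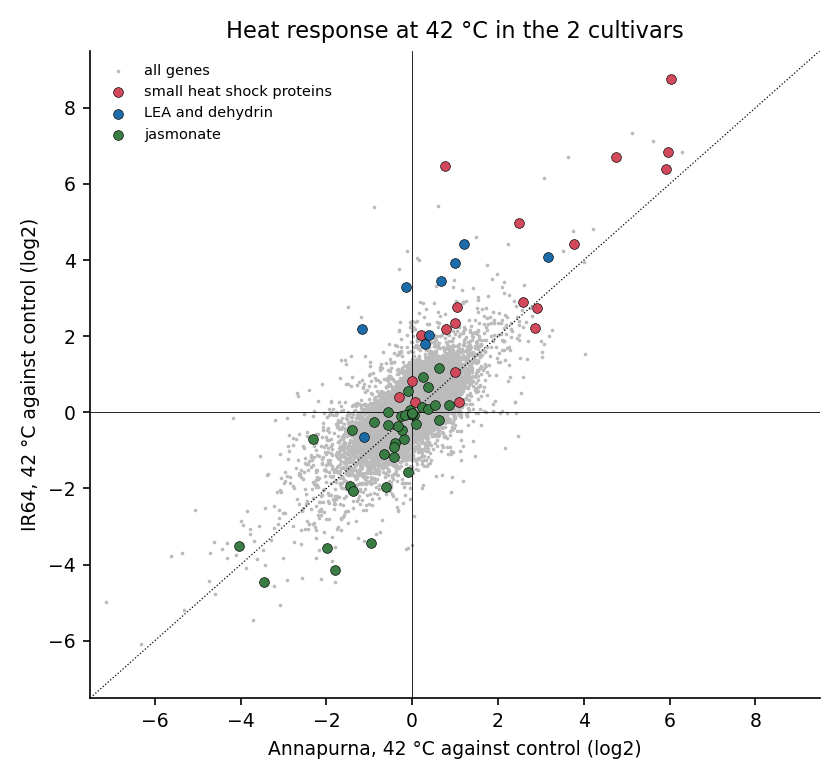
Log2 difference of 42 °C from control in Annapurna (x axis) and IR64 (y axis) for 17905 genes, with members of 3 lists coloured and the dotted line marking equal change. Median log2 of small heat shock proteins is 1.08 in Annapurna and 2.73 in IR64, of LEA and dehydrin genes 0.39 and 3.30, and of jasmonate genes -0.24 and -0.32.

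From 37 °C to 42 °C many of the early heat genes fell in both cultivars. The 42 °C arrays followed 2 h more of heat, so the higher temperature and a change with time could not be told apart. HSFA2A fell (log2 -7.67 ± 0.086 in Annapurna and -6.92 ± 0.086 in IR64), and so did CLPB1 (-4.71 ± 0.083 and -3.94 ± 0.083). Small heat shock proteins fell in Annapurna (0 of 19 rose and 13 fell, or 1 and 16 adjusted over the list alone). With median log2 -2.28 the list had adjusted p = 1.8e-11, and adjusted p = 1.7e-04 with an estimated correlation. In IR64 they fell too (0 of 19 rose and 12 fell, or 3 and 12 adjusted over the list alone). With median log2 -1.61 the list had adjusted p = 3.5e-06, and adjusted p = 0.0032 with an estimated correlation. HSP18.6 stood at log2 -4.99 ± 0.13 and -4.22 ± 0.13. Heat stress transcription factors shifted down in Annapurna (0 of 20 rose and 9 fell, or 1 and 14 adjusted over the list alone). With median log2 -0.93 the list had adjusted p = 3.7e-06, and adjusted p = 0.084 with an estimated correlation. So did those of IR64 (1 of 20 rose and 6 fell, or 4 and 10 adjusted over the list alone). With median log2 -0.29 the list had adjusted p = 0.0056, and adjusted p = 0.21 with an estimated correlation. HSP100 and Clp genes shifted down in Annapurna (0 of 8 rose and 4 fell, or 0 and 5 adjusted over the list alone) and IR64 (0 of 8 rose and 3 fell, or 1 and 6 adjusted over the list alone). With median log2 -1.02 the list had adjusted p = 0.0021 in Annapurna (0.051 with an estimated correlation). The IR64 values were -0.70, 0.0031 and 0.068. ER folding genes shifted down in Annapurna (0 of 24 rose and 8 fell, or 4 and 16 adjusted over the list alone) and IR64 (1 of 24 rose and 6 fell, or 7 and 15 adjusted over the list alone). With median log2 -0.29 the list had adjusted p = 2.4e-04 in Annapurna (0.084 with an estimated correlation). The IR64 values were -0.53, 5.4e-04 and 0.089. BZIP60, a transcription factor of ER stress, fell in Annapurna (log2 -1.97 ± 0.088). Cell division genes shifted up from 37 °C to 42 °C in Annapurna (6 of 65 rose and 1 fell, or 38 and 10 adjusted over the list alone). With median log2 0.27 the list had adjusted p = 0.0031, and adjusted p = 0.21 with an estimated correlation. The same held in IR64 (8 of 65 rose and 0 fell, or 38 and 8 adjusted over the list alone). With median log2 0.26 the list had adjusted p = 0.0059, and adjusted p = 0.24 with an estimated correlation. OsPCNA rose by 1.43 ± 0.045 and 1.57 ± 0.045. PP2C and ABA receptor genes shifted down in Annapurna (1 of 57 rose and 8 fell, or 14 and 27 adjusted over the list alone). With median log2 -0.13 the list had adjusted p = 0.016, and adjusted p = 0.21 with an estimated correlation. They shifted down in IR64 (1 of 57 rose and 6 fell, or 14 and 32 adjusted over the list alone). With median log2 -0.17 the list had adjusted p = 0.0027, and adjusted p = 0.17 with an estimated correlation. PP2C68, of a family of phosphatases in abscisic acid signalling, fell (log2 -3.998 ± 0.16 and -2.44 ± 0.16). LEA and dehydrin genes fell in Annapurna (0 of 9 rose and 7 fell, or 0 and 8 adjusted over the list alone). With median log2 -1.96 the list had adjusted p = 2.4e-05, and adjusted p = 0.12 with an estimated correlation. RAB16B fell (log2 -3.88 ± 0.082). In IR64 6 of 9 rose and 1 fell, or 7 and 1 adjusted over the list alone, and the list was not called (median log2 1.09, adjusted p = 0.051). WRKY factors shifted down in IR64 (0 of 6 rose and 3 fell, or 0 and 4 adjusted over the list alone). With median log2 -0.94 the list had adjusted p = 0.005, and adjusted p = 0.092 with an estimated correlation. OsWRKY71 fell (log2 -3.43 ± 0.097). Chlorophyll synthesis genes shifted down in IR64 (1 of 14 rose and 1 fell, or 1 and 11 adjusted over the list alone). With median log2 -0.34 the list had adjusted p = 0.0026, and adjusted p = 0.17 with an estimated correlation. CHL1 fell (log2 -1.26 ± 0.050), while PORA rose by 1.48 ± 0.055. CBL-interacting and calcium-dependent kinases shifted down in Annapurna (1 of 44 rose and 7 fell, or 8 and 19 adjusted over the list alone). With median log2 -0.080 the list had adjusted p = 0.042, and adjusted p = 0.21 with an estimated correlation. CIPK5 fell (log2 -2.92 ± 0.079), while CIPK10 rose by 2.10 ± 0.13. The same list shifted down in IR64 (1 of 44 rose and 2 fell, or 8 and 21 adjusted over the list alone). With median log2 -0.080 the list had adjusted p = 0.02, and adjusted p = 0.17 with an estimated correlation. Calvin cycle genes shifted down in Annapurna (0 of 7 rose and 2 fell, or 1 and 4 adjusted over the list alone) and IR64 (0 of 7 rose and 2 fell, or 0 and 6 adjusted over the list alone). With median log2 -0.38 the list had adjusted p = 0.042 in Annapurna (0.21 with an estimated correlation). The IR64 values were -0.56, 5.4e-04 and 0.098. Jasmonate genes shifted down too, with 3 of 38 rose and 6 fell, or 8 and 20 adjusted over the list alone in Annapurna and 3 of 38 rose and 7 fell, or 11 and 18 adjusted over the list alone in IR64. With median log2 -0.33 the list had adjusted p = 0.042 in Annapurna (0.21 with an estimated correlation). The IR64 values were -0.065, 0.029 and 0.17. In IR64 NAC factors shifted down (0 of 8 rose and 2 fell, or 1 and 5 adjusted over the list alone). With median log2 -0.46 the list had adjusted p = 0.0059, and adjusted p = 0.081 with an estimated correlation. Raffinose and trehalose synthesis genes shifted down there (1 of 9 rose and 3 fell, or 1 and 5 adjusted over the list alone). With median log2 -0.017 the list had adjusted p = 0.036, and adjusted p = 0.12 with an estimated correlation; the mean was -0.58. In Annapurna histones shifted up as a list (1 of 6 rose and 0 fell, or 6 and 0 adjusted over the list alone). With median log2 0.60 the list had adjusted p = 0.0073, and adjusted p = 0.21 with an estimated correlation. The cytosolic ribosomal protein list shifted up there by a small margin (0 of 24 rose and 0 fell, or 16 and 0 adjusted over the list alone). With median log2 0.16 the list had adjusted p = 0.0062, and adjusted p = 0.21 with an estimated correlation. In Annapurna 803 probe sets were higher and 1769 lower, and in IR64 784 and 1080; 291 higher were shared against 11.0 by chance, and 713 lower against 33.4.

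Between the controls the cultivars differed in single genes more than in lists. OsTPP7, a trehalose-6-phosphate phosphatase gene known as deleted in IR64, read 2264 ± 216 in Annapurna and 4.998 ± 0.0700 in IR64 (log2 6.76 ± 0.089, Annapurna minus IR64), and its other probe set was higher too. BGLU19 (5.46 ± 0.15), the ethylene signalling factor EIL1 (4.34 ± 0.23), RH2 (3.70 ± 0.069), GLP2 (3.43 ± 0.22, its other probe set lower) and OsPP2C12 (3.06 ± 0.16) were higher in Annapurna. OsCASPL1E1 (-6.04 ± 0.080), the calmodulin-like gene CML16 (-4.36 ± 0.13), the chitinase gene Cht1 (-3.85 ± 0.24), CYP714C2 (-3.22 ± 0.15), HSP18.1 (-2.60 ± 0.13) and the cell wall gene OsXTH8 (-2.55 ± 0.16) were higher in IR64. The cytosolic ribosomal protein list was shifted down in Annapurna by a small margin (0 of 24 were higher and 0 lower, or 1 and 16 adjusted over the list alone). With median log2 -0.21 the list had adjusted p = 2.2e-04, and adjusted p = 0.53 with an estimated correlation. No other list was called. In all 1195 probe sets were higher and 841 lower in Annapurna, or 58.7% of calls higher; after quantile normalization 1002 were higher and 1016 lower, or 49.7%.

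At 37 °C the dehydrin RAB16B read 11990 ± 335 in Annapurna and 1003 ± 21.7 in IR64 (log2 3.56 ± 0.082), and LEA and dehydrin genes were higher in Annapurna (5 of 9 were higher and 0 lower, or 8 and 0 adjusted over the list alone). With median log2 1.35 the list had adjusted p = 0.0013, and adjusted p = 0.27 with an estimated correlation. Heat stress transcription factors were shifted up in Annapurna (5 of 20 were higher and 0 lower, or 15 and 0 adjusted over the list alone). With median log2 0.41 the list had adjusted p = 0.0013, and adjusted p = 0.27 with an estimated correlation. HSFB2B stood at log2 2.03 ± 0.11. Jasmonate genes were shifted up (4 of 38 were higher and 0 lower, or 24 and 5 adjusted over the list alone). With median log2 0.45 the list had adjusted p = 0.0047, and adjusted p = 0.23 with an estimated correlation. CM-LOX2, a lipoxygenase gene, differed by 1.59 ± 0.14. PP2C and ABA receptor genes were shifted up (7 of 57 were higher and 0 lower, or 28 and 12 adjusted over the list alone). With median log2 0.18 the list had adjusted p = 0.03, and adjusted p = 0.4 with an estimated correlation, adjusted p = 0.075 after quantile normalization, and 0.057 among probe sets at or above the median level. Clock genes were shifted up as a list (0 of 7 were higher and 0 lower, or 6 and 0 adjusted over the list alone). With median log2 0.44 the list had adjusted p = 0.0054, and adjusted p = 0.4 with an estimated correlation. Expansins and XTH genes, which loosen cell walls, were shifted down in Annapurna (0 of 30 were higher and 3 lower, or 1 and 24 adjusted over the list alone). With median log2 -0.43 the list had adjusted p = 6.1e-07, and adjusted p = 0.23 with an estimated correlation. OsXTH8 stood at -2.74 ± 0.16. The ribosomal protein list was shifted down (0 of 24 were higher and 0 lower, or 0 and 13 adjusted over the list alone). With median log2 -0.13 the list had adjusted p = 0.0017, and adjusted p = 0.27 with an estimated correlation. HSP18.1 averaged 128 ± 12.1 in Annapurna and 33560 ± 1640 in IR64 (log2 -7.87 ± 0.13), and its other probe set was lower too. OsTPP7 (4.81 ± 0.089), the metal transporter gene Nramp1 (4.01 ± 0.11), the sugar transporter gene OsSWEET15 (3.65 ± 0.12), RH2 (3.60 ± 0.069) and OsPP2C12 (3.18 ± 0.16) were higher in Annapurna. OsCASPL1E1 (-5.87 ± 0.080), CML16 (-4.18 ± 0.13), Cht1 (-3.45 ± 0.24), the endoglucanase gene GLU15 (-3.35 ± 0.10) and CYP714C2 (-2.84 ± 0.15) were lower. In all 1030 probe sets were higher and 770 lower in Annapurna.

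At 42 °C the LEA difference had the opposite sign: 0 of 9 were higher and 8 lower, or 0 and 9 adjusted over the list alone in Annapurna. With median log2 -1.95 the list had adjusted p = 5.2e-06, and adjusted p = 0.07 with an estimated correlation. RAB16C read 212 ± 4.13 in Annapurna and 2282 ± 217 in IR64 (log2 -3.33 ± 0.17), OsPM19L1 differed by -2.43 ± 0.13 and rab25 by -2.29 ± 0.12, on arrays where AMY1.1 differed by -8.77 ± 1.19 and the seed-type tonoplast aquaporin gene OsTIP3;1 by -3.69 ± 0.074. Small heat shock proteins were shifted down in Annapurna (1 of 19 were higher and 5 lower, or 4 and 13 adjusted over the list alone). With median log2 -0.53 the list had adjusted p = 0.0041, and adjusted p = 0.062 with an estimated correlation. HSP26.7 differed by -2.72 ± 0.049, HSP16.9B by -2.60 ± 0.076 and HSP18.1 by -8.32 ± 0.13. WRKY factors were higher in Annapurna (4 of 6 were higher and 0 lower, or 4 and 1 adjusted over the list alone). With median log2 1.80 the list had adjusted p = 0.0012, and adjusted p = 0.063 with an estimated correlation. OsWRKY76 stood at 2.38 ± 0.15. Jasmonate genes were shifted up too (5 of 38 were higher and 2 lower, or 19 and 5 adjusted over the list alone). With median log2 0.22 the list had adjusted p = 0.0012, and adjusted p = 0.063 with an estimated correlation. JAZ10 differed by 2.21 ± 0.11. Calvin cycle genes were shifted up in Annapurna (2 of 7 were higher and 0 lower, or 5 and 0 adjusted over the list alone). With median log2 0.52 the list had adjusted p = 4.1e-04, and adjusted p = 0.081 with an estimated correlation. CFBP1, listed by symbol, differed by 1.28 ± 0.072. Chlorophyll synthesis genes were shifted up (1 of 14 were higher and 0 lower, or 9 and 1 adjusted over the list alone). With median log2 0.23 the list had adjusted p = 0.0012, and adjusted p = 0.19 with an estimated correlation. Light reaction genes were shifted up as a list (0 of 10 were higher and 0 lower, or 5 and 0 adjusted over the list alone). With median log2 0.11 the list had adjusted p = 0.021, and adjusted p = 0.34 with an estimated correlation. NAC genes were so too (0 of 8 were higher and 0 lower, or 6 and 0 adjusted over the list alone). With median log2 0.42 the list had adjusted p = 0.0014, and adjusted p = 0.062 with an estimated correlation. Raffinose and trehalose synthesis genes were shifted up (2 of 9 were higher and 0 lower, or 4 and 1 adjusted over the list alone). With median log2 0.21 the list had adjusted p = 0.035, and adjusted p = 0.096 with an estimated correlation. OsTPP7 stood at log2 5.37 ± 0.089. OsPP2C12 (4.17 ± 0.16), RH2 (4.06 ± 0.069), Nramp1 (3.77 ± 0.11), EIL1 (3.73 ± 0.23) and OsPMEI28 (3.46 ± 0.099) were higher, and GLU15 (-4.64 ± 0.10), OsCASPL1E1 (-4.61 ± 0.080) and Cht1 (-4.14 ± 0.24) lower. In all 823 probe sets were higher and 1106 lower in Annapurna.

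**Figure D4:**
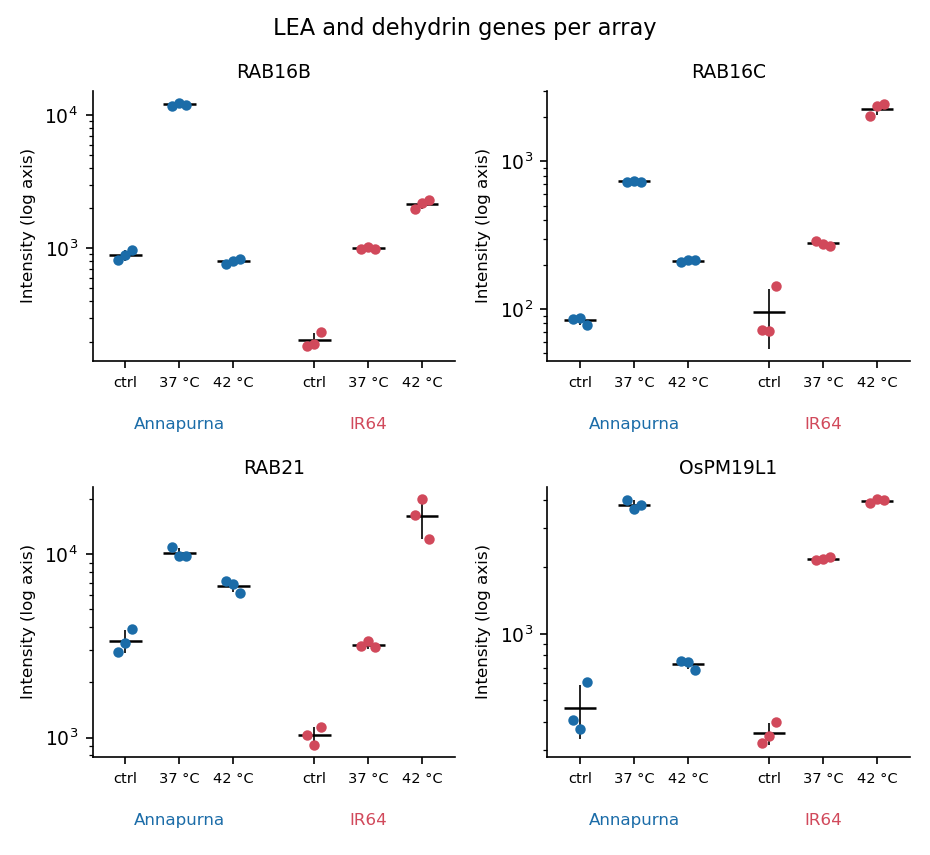
Intensity on a log axis of 4 LEA and dehydrin genes in each group, with points for the 3 arrays, horizontal bars for means and vertical bars for ± 1 SD. RAB16B averages 11990 in Annapurna at 37 °C and 798 at 42 °C, against 1003 and 2153 in IR64.

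Whether the heat response itself differed was tested as the Annapurna response minus the IR64 response, where higher means a change further up, or less far down, in Annapurna, and lower the reverse. At 37 °C the rise of LEA and dehydrin genes was larger in Annapurna (5 of 9 were higher and 0 lower, or 7 and 0 adjusted over the list alone). With median log2 1.03 the list had adjusted p = 1.9e-04, and adjusted p = 0.38 with an estimated correlation. EM differed by 1.67 ± 0.38 and RAB16B by 1.51 ± 0.12. Jasmonate responses were shifted up in Annapurna (6 of 38 were higher and 1 lower, or 14 and 5 adjusted over the list alone). With median log2 0.13 the list had adjusted p = 0.0044, and adjusted p = 0.3 with an estimated correlation. Of 2 genes that carry the symbol AOS, of jasmonate synthesis, the one also named AOS1 differed by 1.87 ± 0.19 and AOS2 by -1.07 ± 0.12, and JAZ11 differed by 1.56 ± 0.13. FTSH6, a plastid protease gene (2.85 ± 0.14), OsPP2C51 (2.20 ± 0.036, its other probe set not called), OsPHT3 (2.09 ± 0.13), NAAT1 of iron chelator synthesis (1.80 ± 0.21) and HSFB2B (1.80 ± 0.15, its other probe set not called) had higher responses in Annapurna. HSP18.1 (-5.26 ± 0.19), BGLU19 (-2.91 ± 0.21), the amylase gene AMY1.3 (-2.59 ± 0.100, its other probe set not called), PDX12 (-2.19 ± 0.10), CML14 (-2.07 ± 0.21) and OsTPP7 (-1.95 ± 0.13) had lower responses in Annapurna. FTSH6, OsPP2C51, AOS2, BGLU19 and OsTPP7 read below 50 in both IR64 groups, so these differences rest on the change in Annapurna, and no response can be read in IR64. HSP18.1 read lower in Annapurna than in IR64 at every step, so a sequence difference at its probes was not separated from a weaker response. By count 454 probe sets were higher and 373 lower.

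At 42 °C the responses of LEA and dehydrin genes were lower in Annapurna (0 of 9 were higher and 7 lower, or 0 and 9 adjusted over the list alone). With median log2 -2.77 the list had adjusted p = 4.5e-05, and adjusted p = 0.2 with an estimated correlation. RAB16B stood at log2 -3.46 ± 0.12, and AMY1.1 differed by -6.30 ± 1.68, with values from -5.27 to -8.29 when 1 control array was left out, the last without IR64 control replicate 3. Responses of small heat shock proteins were shifted down in Annapurna (0 of 19 were higher and 8 lower, or 3 and 14 adjusted over the list alone). With median log2 -0.84 the list had adjusted p = 0.001, and adjusted p = 0.034 with an estimated correlation. HSP18.1 stood at log2 -5.72 ± 0.19 and HSP26.7 at -2.74 ± 0.070. Those of heat stress transcription factors were shifted down too (0 of 20 were higher and 5 lower, or 1 and 13 adjusted over the list alone). With median log2 -0.70 the list had adjusted p = 0.018, and adjusted p = 0.37 with an estimated correlation. HSFA2C stood at log2 -1.75 ± 0.23. CLPB1 differed by -1.05 ± 0.12 and HSFA2A by -1.003 ± 0.12, calls that quantile normalization ended (-0.87 for both). The call of CLPB1 also ended without Annapurna control replicate 3 (-0.92) or IR64 42 °C replicate 1 (-0.99), and that of HSFA2A without replicate 1 of either control, replicates 1 or 3 of Annapurna 42 °C, or replicates 1 or 2 of IR64 42 °C (-0.92 to -0.998). WRKY responses were shifted up in Annapurna (2 of 6 were higher and 0 lower, or 4 and 1 adjusted over the list alone). With median log2 0.78 the list had adjusted p = 0.024, and adjusted p = 0.25 with an estimated correlation. Jasmonate responses were shifted up too (6 of 38 were higher and 1 lower, or 18 and 8 adjusted over the list alone). With median log2 0.16 the list had adjusted p = 0.0085, and adjusted p = 0.2 with an estimated correlation. JAZ12 differed by 2.49 ± 0.15 and JAZ10 by 2.35 ± 0.15. Histone responses were shifted up (1 of 6 were higher and 0 lower, or 6 and 0 adjusted over the list alone). With median log2 0.51 the list had adjusted p = 0.0029, and adjusted p = 0.37 with an estimated correlation. Calvin cycle responses were shifted up as a list (0 of 7 were higher and 0 lower, or 5 and 1 adjusted over the list alone). With median log2 0.29 the list had adjusted p = 0.026, and adjusted p = 0.37 with an estimated correlation. So were chlorophyll synthesis responses (1 of 14 were higher and 0 lower, or 8 and 2 adjusted over the list alone). With median log2 0.21 the list had adjusted p = 0.039, and adjusted p = 0.45 with an estimated correlation. Ribosomal protein responses were shifted up as a list by a small margin (0 of 24 were higher and 0 lower, or 9 and 0 adjusted over the list alone). With median log2 0.10 the list had adjusted p = 0.0021, and adjusted p = 0.31 with an estimated correlation. CYP71Z7, of phytocassane synthesis (3.098 ± 0.40), the nicotianamine synthase genes NAS2 (3.08 ± 0.17) and NAS1 (3.01 ± 0.057) and OsPHT3 (2.63 ± 0.13) had higher responses in Annapurna, and ELA3 (-4.27 ± 0.22), BGLU19 (-4.03 ± 0.21) and OsTIP3;1 (-3.84 ± 0.11) lower ones. Below 50 in both groups, where no response can be read, were HSP18.1 in Annapurna, BGLU19 in IR64 and HSFA2A in each. AMY1.1 in Annapurna was so but for control replicate 3 (124). By count 615 probe sets were higher and 1115 lower, or 35.5% of calls higher; after quantile normalization 822 were higher and 801 lower, or 50.6%.

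Between 37 °C and 42 °C the change of LEA and dehydrin genes was lower in Annapurna (0 of 9 were higher and 8 lower, or 0 and 9 adjusted over the list alone). With median log2 -3.23 the list had adjusted p = 1.1e-08, and adjusted p = 0.057 with an estimated correlation. RAB16B, RAB16C and rab25 differed by -4.97 ± 0.12, -4.68 ± 0.24 and -4.47 ± 0.17, and AMY1.1 by -8.76 ± 1.68. The change of small heat shock proteins was shifted down too (0 of 19 were higher and 7 lower, or 3 and 15 adjusted over the list alone). With median log2 -0.77 the list had adjusted p = 3.9e-04, and adjusted p = 0.026 with an estimated correlation. HSP16.9B differed by -3.15 ± 0.11. That of heat stress transcription factors was shifted down (0 of 20 were higher and 5 lower, or 0 and 14 adjusted over the list alone). With median log2 -0.51 the list had adjusted p = 3.3e-04, and adjusted p = 0.17 with an estimated correlation. HSFB2B differed by -2.997 ± 0.15. LTP-2 (-4.85 ± 0.13) and OsSWEET15 (-4.59 ± 0.17) were lower, and CYP71Z7 (2.51 ± 0.40), OsWRKY24 (2.49 ± 0.14), NAS1 (2.35 ± 0.057), OrysaZxb (2.32 ± 0.69), the potassium transporter gene HAK17 (2.07 ± 0.20) and the pathogenesis-related gene PBZ1 (2.06 ± 0.23) higher. AMY1.1 read below 50 in both Annapurna groups and OrysaZxb in both IR64 groups. WRKY changes were higher in Annapurna (4 of 6 were higher and 0 lower, or 4 and 1 adjusted over the list alone). With median log2 1.05 the list had adjusted p = 0.0036, and adjusted p = 0.1 with an estimated correlation. Calvin cycle changes were shifted up as a list (0 of 7 were higher and 0 lower, or 4 and 0 adjusted over the list alone). With median log2 0.43 the list had adjusted p = 0.01, and adjusted p = 0.32 with an estimated correlation. Chlorophyll synthesis (0 of 14 were higher and 0 lower, or 7 and 1 adjusted over the list alone) and ribosomal protein changes (0 of 24 were higher and 0 lower, or 8 and 1 adjusted over the list alone) were shifted up as lists. With median log2 0.22 the list had adjusted p = 0.0085, and adjusted p = 0.39 with an estimated correlation for the former. With median log2 0.083 the list had adjusted p = 0.033, and adjusted p = 0.47 with an estimated correlation for the latter. Expansins and XTH changes were shifted up as a list (1 of 30 were higher and 0 lower, or 11 and 3 adjusted over the list alone). With median log2 0.014 the list had adjusted p = 0.017, and adjusted p = 0.45 with an estimated correlation; the mean was 0.15. By count 553 probe sets were higher and 998 lower, or 35.7% of calls higher; after quantile normalization 711 were higher and 814 lower, or 46.6%.

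**Figure D5:**
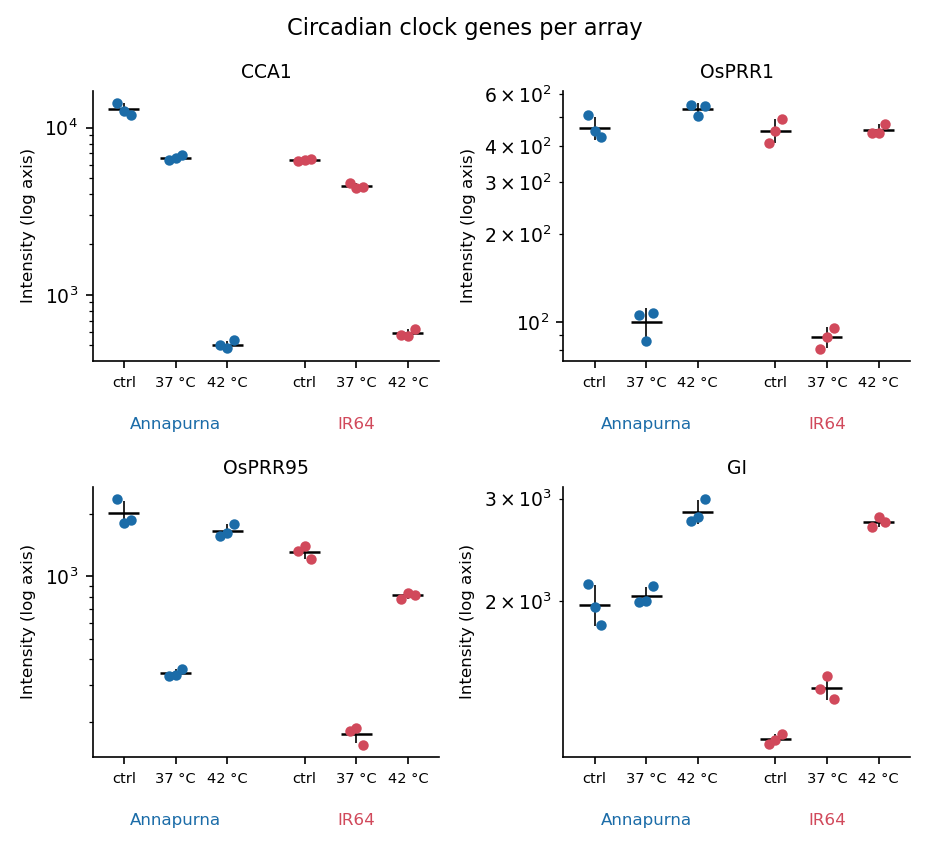
Intensity on a log axis of 4 circadian clock genes in each group, with points for the 3 arrays, horizontal bars for means and vertical bars for ± 1 SD. CCA1 averages 12850 in Annapurna controls and 504 at 42 °C, and OsPRR1 461 in those controls, 99.99 at 37 °C and 536 at 42 °C.

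Clock genes moved apart by step. OsPRR1, the rice relative of the evening gene TOC1, fell at 37 °C (log2 -2.04 ± 0.088 in Annapurna and -2.16 ± 0.088 in IR64), and so did OsPRR95 (-2.48 ± 0.094 and -2.81 ± 0.094). At 42 °C OsPRR1 was at 0.21 ± 0.088 and 0.0097 ± 0.088. CCA1 was at -0.95 ± 0.059 at 37 °C in Annapurna, with a call after quantile normalization (-1.06) or without Annapurna control replicate 3 (-1.01). CCA1 in IR64 stood at -0.51 ± 0.059 at 37 °C, not called. OsPRR95 was at -0.26 ± 0.094 and -0.68 ± 0.094 at 42 °C, not called. OsPRR37 (-0.15 ± 0.074 and -0.096 ± 0.074 at 37 °C, -0.75 ± 0.074 and -0.34 ± 0.074 at 42 °C) and OsPRR73 (0.44 ± 0.039 and 0.093 ± 0.039, 0.35 ± 0.039 and -0.16 ± 0.039) were not called in either cultivar. GI was at 0.052 ± 0.053 and 0.29 ± 0.053 at 37 °C and 0.53 ± 0.053 at 42 °C in Annapurna, not called, and rose in IR64 at 42 °C by 1.22 ± 0.053. As a list clock genes were not called in the heat comparisons with control: in Annapurna at 37 °C 0 of 7 rose and 2 fell, or 1 and 4 adjusted over the list alone, with median log2 -0.65, adjusted p = 0.29, and at 42 °C in IR64 1 of 7 rose and 1 fell, or 1 and 4 adjusted over the list alone, with median log2 -0.16, adjusted p = 0.35.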

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

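The tests with cultivar and step means removed and those that use AMY1.1 were chosen only after the results were seen; the others were planned. Unless another is named, the comparison here is the difference of heat responses, Annapurna minus IR64. Called members are counted above.

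Of 57258 probe sets, 827 differed in their response at 37 °C, 1730 at 42 °C and 1551 between 37 °C and 42 °C. With the cultivar labels exchanged within each step, 10, 10 and 9 of 100 splits gave as many, and the highest other splits gave 5254, 4487 and 4047, several times the real counts. Such counts point to a structure of the samples: the splits other than the real one that reached it all exchanged at least 2 more arrays at 1 step than at the other, so the difference between the cultivars itself entered them. With cultivar and step means removed first, 1 of 100 splits of the 12 arrays, the real one, gave as many in each of the 3 comparisons (762, 1677 and 1530 against highest others of 25, 540 and 0), a share under 0.05. For the 9 comparisons of 3 arrays with 3 there are 10 splits, too few for a share under 0.05; 1 split, the real one, gave as many in each, with 2935, 2640 and 2572 calls in Annapurna (37 °C, 42 °C and 42 °C against 37 °C), 2709, 3561 and 1864 in IR64, and 2036, 1800 and 1929 between cultivars (control, 37 °C and 42 °C). The highest other split gave 1 for Annapurna at 42 °C and for the cultivars at control, and 0 in the other 7.

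LEA and dehydrin responses were shifted up in Annapurna at 37 °C (median 1.03, adjusted p = 0.38 with an estimated correlation). They were shifted down at 42 °C (-2.77, 0.2) and between the heat steps (-3.23, 0.057). So were levels against IR64 at 42 °C (-1.95, 0.07). Array scaling stays open: the median of levels at 42 °C stayed at -1.89 after quantile normalization, which could hardly move so large a median. RNA from grain tissue cannot be told apart from a heat effect for the rise at 37 °C: AMY1.1 read at most 5.65, and of 18 seed and endosperm markers 1 rose in Annapurna and 2 in IR64, but AMY1.3 was among them in both (2.10 and 4.69, against median LEA rises of 2.32 and 1.63) and OsTIP3;1 rose in IR64 (2.37). For the excess in IR64 at 42 °C it cannot be told apart from a cultivar difference: AMY1.1 was high on those arrays, and IR64 control replicate 3, with AMY1.1 at 37.8% of their mean, showed a median LEA difference of 0.24 against 3.30 at 42 °C, but this is 1 array. A difference between the cultivars in drying or in abscisic acid signalling may also contribute and was not tested.

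Responses of small heat shock proteins were shifted down as a list in Annapurna at 42 °C (median -0.84) and between 37 °C and 42 °C (-0.77, where the median was -2.28 in Annapurna and -1.61 in IR64). These calls held with an estimated correlation, and those of the other lists in this part did not. AMY1.1 was high on the IR64 42 °C arrays. For all lists at 42 °C grain RNA was thus not separated from a difference in heat response. Below, the adjusted p with an estimated correlation follows each median. Responses of heat stress transcription factors were shifted down, at -0.70 (0.37) and -0.51 (0.17). Jasmonate responses were shifted up as a list in Annapurna at 37 °C (0.13, 0.3) and 42 °C (0.16, 0.2). WRKY responses were shifted up at 42 °C (0.78, 0.25) and between the heat steps (1.05, 0.1). So were Calvin cycle (0.29, 0.37 and 0.43, 0.32) and chlorophyll synthesis responses (0.21, 0.45 and 0.22, 0.39). Cytosolic ribosomal protein (0.10, 0.31 and 0.083, 0.47) and, at 42 °C, histone responses (0.51, 0.37) were too. Those of expansins and XTH were so between the heat steps (0.014, 0.45).

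Single genes with the largest differences at 37 °C were FTSH6 (2.85), OsPP2C51 (2.20), OsPHT3 (2.09), AOS (1.87, the gene also named AOS1), NAAT1 (1.80) and HSFB2B (1.80), higher in Annapurna, and HSP18.1 (-5.26), BGLU19 (-2.91), AMY1.3 (-2.59), PDX12 (-2.19), CML14 (-2.07) and OsTPP7 (-1.95), lower. At 42 °C they were CYP71Z7 (3.098), NAS2 (3.08), NAS1 (3.01), OsPHT3 (2.63), JAZ12 (2.49) and JAZ10 (2.35), higher, and AMY1.1 (-6.30), HSP18.1 (-5.72), ELA3 (-4.27), BGLU19 (-4.03), OsTIP3;1 (-3.84) and RAB16B (-3.46), lower. AMY1.1 stood at -8.29 without IR64 control replicate 3. Between 37 °C and 42 °C they were CYP71Z7 (2.51), OsWRKY24 (2.49), NAS1 (2.35), OrysaZxb (2.32), HAK17 (2.07) and PBZ1 (2.06), higher, and AMY1.1 (-8.76), RAB16B (-4.97), LTP-2 (-4.85), RAB16C (-4.68), OsSWEET15 (-4.59) and rab25 (-4.47), lower. Some of these genes read below 50 in both compared groups of 1 cultivar, so their differences rest on the other. In IR64 they were FTSH6, OsPP2C51 and OsTPP7 at 37 °C, BGLU19 at both steps and OrysaZxb between them. In Annapurna they were HSP18.1 at 42 °C and AMY1.1 between the steps. At 42 °C AMY1.1 did so but for control replicate 3 (124).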

How the results depend on the processing

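Leaving out control replicate 3 of both cultivars and the filter above 50 in both were chosen after the data were seen, and the other settings were planned. Series of 12 counts run in the order Annapurna 37 °C, 42 °C and 42 °C against 37 °C, the same in IR64, the cultivars at control, 37 °C and 42 °C, and the difference of responses at 37 °C, 42 °C and 42 °C against 37 °C. Quantile normalization, median centring, the filter on the median level, no variance trend, array weights and fits to the compared groups alone left all 12 counts within 1.5 times the main ones, and no named gene reversed under any alternative in which named genes were followed, which array weights and fits to the compared groups were not. Quantile normalization shared the largest part of the calls at the first comparison (2894 of 2935) and the smallest for the difference of responses at 42 °C (1411 of 1730); of 1388 named results it ended 28 calls and added 4, and a pseudocount of 64 ended 117.

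Without a fold threshold the 12 counts were 15549, 15128, 14461, 29634, 42612, 36965, 38808, 30644, 11819, 6332, 36044 and 26411, since small differences then count, and 45.9, 50.4, 55.6, 27.7, 26.9, 28.5, 25.3, 25.8, 43.7, 48.2, 74.2 and 72.4% of calls were higher against 56.2, 43.1, 31.2, 57.3, 58.6, 42.1, 58.7, 57.2, 42.7, 54.9, 35.5 and 35.7%, so the larger share changed sides in all but the sixth and ninth. For IR64 at 42 °C 42612 of 57258 probe sets passed, while 34.2 to 35.3% on an array exceeded 50, so many lay near background. Array medians ran from 7.97 to 8.17 in IR64 controls and from 7.57 to 7.73 in IR64 at 42 °C. A small shift of weak probe sets between groups thus enters these counts and their balance. With 1 probe set per gene, which tests fewer probe sets, the 12 counts were 1846, 1588, 1634, 1652, 2064, 1150, 1096, 966, 996, 508, 987 and 914. A pseudocount of 64, which shrinks differences of weak probe sets, gave 1752, 1774, 2318, 1183, 1218, 1164, 1184, 452, 980 and 944 for all but the first and the third comparison, and a pseudocount of 1 gave 1276 and 2653 for the difference of responses at 37 °C and 42 °C, since it widens differences of weak probe sets. Probe sets above 50 in both cultivars gave 1347, 1106 and 1189 cultivar differences, with fewer probe sets tested. Of 456 list tests, 89 were called with the preset correlation, 8 with an estimated correlation and 364 by fry, which does not compare a list with other genes; the call rests on the correlation assumed.

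Leaving out 1 array gave 2892 to 3012, 2592 to 2723, 2530 to 2620, 2673 to 2801, 3418 to 3675, 1866 to 1905, 1946 to 2187, 1793 to 1818, 1918 to 1972, 802 to 864, 1651 to 1907 and 1502 to 1650 calls in the 12 comparisons. Without control replicate 3 of both cultivars the differences of responses numbered 839 at 37 °C and 1831 at 42 °C. With the replicate number as a replicate block the counts were 2935, 2640, 2571, 2709, 3561, 1864, 2036, 1800, 1925, 824, 1730 and 1546. No pair of groups had all 3 residual correlations between arrays of equal number above 0.1. The replicate numbers thus gave no clear sign of pairing, though this cannot exclude it. No difference can be read for genes below an intensity of 50 in all groups.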

Other observations

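The tests of the clock genes, the test of sequence difference on bright probe sets alone and the test of scaling by direction were chosen only after the result was seen or the prediction written; the other tests of probe sets near background were planned.

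Among ethylene response and DREB factors, 1 of 10 rose and 4 fell, or 2 and 5 adjusted over the list alone in Annapurna at 37 °C (median log2 -0.084, adjusted p = 0.52), and DREB1A fell at 42 °C (log2 -3.47 ± 0.13 in Annapurna and -3.62 ± 0.13 in IR64). Of the root markers, 5 of 28 rose and 3 fell, or 9 and 13 adjusted over the list alone in IR64 at 42 °C (median log2 -0.014, adjusted p = 0.53, mean log2 0.065): the silicon channel gene Lsi1 rose (3.08 ± 0.17), while NAAT1 (-2.60 ± 0.15) and NAS1 (-2.10 ± 0.040), of iron chelator synthesis, fell; in Annapurna NAS2 rose (2.46 ± 0.12). The seed and endosperm markers at the same step held AMY1.1, GLB1 (2.51 ± 0.078) and AMY1.3 (2.04 ± 0.071): 4 of 18 rose and 0 fell, or 7 and 7 adjusted over the list alone (median log2 -0.010, adjusted p = 0.84, mean log2 0.68). Of the aquaporins, 4 of 25 rose and 1 fell, or 14 and 7 adjusted over the list alone in IR64 at 37 °C (median log2 0.12, adjusted p = 0.098), OsTIP3;1 by 2.37 ± 0.074. Of the chitinases, 2 of 12 rose and 0 fell, or 6 and 0 adjusted over the list alone in Annapurna at 42 °C (median log2 0.18, adjusted p = 0.11), Cht1 by 1.61 ± 0.24. Cellulose and lignin synthesis genes in Annapurna at 37 °C split, as 3 of 56 rose and 5 fell, or 11 and 26 adjusted over the list alone (median log2 -0.12, adjusted p = 0.4), with LAC7 at 2.50 ± 0.12 and CAD3 at -1.74 ± 0.048. Auxin response genes did too (6 of 58 rose and 9 fell, or 15 and 31 adjusted over the list alone; median log2 -0.19, adjusted p = 0.15), with OsPIN5a at -2.76 ± 0.095 and OsPIN5 at 2.03 ± 0.091.

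In cytokinin signalling 1 of 16 rose and 4 fell, or 6 and 8 adjusted over the list alone in Annapurna at 37 °C (median log2 -0.13, adjusted p = 0.78), and the response regulator gene OsRR9 fell (-2.51 ± 0.079). Of the CCCH zinc finger proteins 3 of 50 rose and 2 fell, or 14 and 22 adjusted over the list alone (median log2 -0.077, adjusted p = 0.8), OsC3H35 by 2.79 ± 0.079; of the thioredoxins and glutaredoxins 5 of 38 rose and 3 fell, or 14 and 19 adjusted over the list alone (median log2 -0.19, adjusted p = 0.97; mean log2 0.014), GRXC10 by 1.61 ± 0.12. Of the stress associated A20/AN1 proteins 2 of 13 rose and 0 fell, or 6 and 1 adjusted over the list alone in IR64 at 37 °C (median log2 0.16, adjusted p = 0.073), OsSAP5 by 1.23 ± 0.12. Of the glutathione S-transferases 1 of 6 rose and 1 fell, or 4 and 1 adjusted over the list alone in IR64 at 42 °C (median log2 0.22, adjusted p = 0.52), GST1 by 2.14 ± 0.11. Ubiquitin and proteasome genes moved little in Annapurna at 37 °C (1 of 31 rose and 0 fell, or 4 and 7 adjusted over the list alone; median log2 -0.061, adjusted p = 0.97; mean log2 0.016), OsUBC5b by 1.66 ± 0.063. Actin and tubulin reference genes were not all steady: 2 of 14 rose and 0 fell, or 4 and 7 adjusted over the list alone (median log2 -0.17, adjusted p = 0.8; mean log2 0.025), TUB7 by 1.41 ± 0.084 and ACT7 by 1.095 ± 0.088.

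The clock genes CCA1, OsPRR1 and OsPRR95 departed from control at different steps. CCA1 fell at 42 °C (-4.63 ± 0.059 in Annapurna and -3.41 ± 0.059 in IR64), where elapsed time was 3 h as in the control and does not enter the comparison. For OsPRR1 and OsPRR95 at 37 °C an elapsed time of 1 h against 3 h cannot be told apart from heat, since at 42 °C, with elapsed time equal to control, both lay within 1 log2 of it (farthest -0.68). The hour of the day at sampling is not given in the sources used here, and a heat effect on the clock may account for part of the pattern and stays open.

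Of the 2036 probe sets called between the controls of the cultivars, 778 (38.2%) were called in 1 direction at all 3 steps, and 139 of these read below 50 in every group of 1 cultivar and at least 3 log2 apart at every step, OsTPP7 among them. Scaling of whole arrays, which keeps the order of the probe sets on an array, is argued against, since 63 of the 139 were higher in Annapurna and 76 in IR64. The authors' background step stays open: 100% of the 139 stayed called after quantile normalization, but probe sets chosen as 3 log2 apart could hardly lose their call. A sequence difference at the probes fits by the test as planned: of 21 other probe sets of the same genes, 9 (42.9%) were called the same way at all 3 steps, under the 50% set beforehand. Of the 21, 7 read below 50 in every group and could hardly be called; among the 14 brighter ones the share was 64.3%, between the bounds, so a difference in transcript level may also occur and stays open.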
